A study of Arabidopsis thaliana with 12 samples.

How the data were processed

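Spot intensities of 12 samples of Arabidopsis thaliana, ecotype Columbia 0, were used: 6 from the wild type (WT) and 6 from the pam48 mutant, each numbered 1 to 6 in the sample titles. The molecule was total RNA, per the labels. The deposited table held 1 intensity per probe and sample for 3439 probes, on a linear scale that ran in every sample from 0 to 100, with several spots sharing the value 100. The labelling, scanner, background correction and normalisation behind these values are not given in the sources used here. Between 3 and 7 spots per sample stood at the maximum, where intensities have only a lower bound, and between 143 and 385 were exactly 0. Sample medians differed by up to 1.74 on the log2 scale, so the scale had not brought the samples to a common level.

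Group membership came from the sample titles. The choices below were made before the data were examined unless stated otherwise. Because medians differed by more than 0.1 (log2), intensities were quantile normalised between samples. Every value below a sample's 5th percentile of positive values was then raised to that percentile, called the floor here, and log2 was taken. On this scale the deposited maximum of 100 is 6.64. After normalisation the floor lay between -6.13 and -4.43, lowest in pam48 samples 3 and 4, and between 8.96% and 15.6% of probes per sample were at it. A probe at the floor in all 6 samples of a genotype gives only a bound, and a probe at the floor in all 12 gives no fold. No probe could be identified as a control spot, so all 3439 were tested. The number of samples, not a read depth, limits the precision.

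Genotypes were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, pam48 minus WT, two-sided), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05, taking each of the 12 columns as a sample. No covariate was used. Zeros and positive values below the floor were treated alike, so that a zero does not outrank a low positive value. The design allowed consecutive numbers to be averaged if their difference had an SD under 50% of the smallest SD between other columns of the genotype. It did not: the widest SD within consecutive numbers was 0.631 against a limit of 0.480 in WT, and 0.618 against 0.400 in pam48. All the same, each of the 12 columns was nearest to the column with the consecutive number (1 with 2, 3 with 4, 5 with 6), so results are also given with those couples of columns averaged and with them as a random block (duplicateCorrelation). The labels do not say whether the numbered samples came from separate plants, so the p-values measure only the spread between these samples, which may be technical. WT and pam48 samples of the same number deviated together from their genotype means in all 6 cases (r across probes 0.188 to 0.418). By the rule set before the data were examined, the numbers therefore pair the samples, although the labels do not say what a number marks. The highest r with another number was nearly as high (0.165 to 0.368). Outside the couple of consecutive numbers it was at most 0.077. The pairing may therefore lie in the couples, and the replicate block still counts consecutive columns as separate samples.

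Probes were named from the platform annotation supplied with the series, with symbols updated through Entrez Gene identifiers to the TAIR10.1 gene table. Of the 3439 probes, 692 had 1 gene, 870 had several genes and were not named, and 1877 were not listed there. Of the 692, 690 matched a locus. The build behind the probes is not given in the sources used here, so no coordinates are printed. On an array of this kind, related transcripts can hybridise to 1 spot, which the values cannot separate. Genes were named by a fixed rule: the 8 largest changes in each direction among called 1-gene probes whose samples all lay on their own side of the other genotype's mean, and the 2 members with the smallest p in each gene list. The 16 gene lists (339 loci) covered light harvesting, photosystem I, photosystem II, electron transport with ATP synthase, the Calvin cycle, tetrapyrroles, isoprenoids with carotenoids, plastid translation, plastid import with chaperones and proteases, antioxidants, starch, plastid amino acid synthesis, lipids with oxylipins, plastid transcription, photorespiration, and markers of non-green plastids or senescence. Only 18 loci had a 1-gene probe, and 7 lists had none and gave no result: electron transport, isoprenoids, import, starch, plastid transcription, photorespiration and the markers of other cell types or states. A list was tested with camera (preset correlation 0.01) only with 4 or more measured members, which left 1 list.

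On simulated values for the 3439 probes with 200 changed ones, the test with 12 independent samples recovered 91% of changes of 2 and 33% of changes of 1 on the log2 scale, with 9 false calls. On simulated values with no genotype difference, in which the columns of a couple shared a hybridisation effect as wide as the observed one, the same test made a median of 79 calls over 20 runs (53 to 113), the random block a median of 2 and the averaged couples a median of 0. That effect was drawn for each probe on its own. Effects shared by many probes could give more calls, so 53 to 113 is no limit for chance. Camera detected 100 of 100 lists of 6 probes lowered by 1 and called 4 of 100 unshifted ones. Probes and columns were independent in that simulation. The 1 list tested had an estimated correlation of 0.40 between its genes, so these rates need not hold for it. Alternatives covered scaling (values as deposited, median centring, cyclic loess), the treatment of low values, the replicate number as a block, averaging or random blocks for consecutive numbers, array weights, the variance prior, an exact permutation test, thresholds, and leaving out each sample. A common floor, probes above the floor only, averaged couples with a block, leaving out a couple of numbers, and leaving out the list member at the floor were added after seeing the data.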

Results

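Transcript levels in the pam48 mutant of Arabidopsis, described in the labels as altered in photosynthesis and defective in a protein that they do not name, were compared with those in the wild type (WT) of the same ecotype, with 6 samples per genotype on arrays of 3439 probes. The labels do not name the mutated gene, so its own transcript could not be used to check them. On the deposited scale, on which each sample's brightest spots stand at 100, median intensity ran from 0.0913 to 0.192 in WT and from 0.233 to 0.305 in pam48. Of the 18 plastid genes asked about that had a probe with 1 gene, 10 lay in the brightest 25% of probes, at a median percentile of 78.2, from PSBW at 99.7 down to AT5G65220, which lay at the floor in all 12 samples.

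The comparison asks which transcripts differ between pam48 and WT. PRK, which encodes phosphoribulokinase of the Calvin cycle, was 5.27-fold lower in pam48 than in WT, a log2 change of -2.40 ± 0.24 (SE, 6 samples per genotype; limma, adjusted p = 2.2e-04), with no overlap between the genotypes. AT3G53580, the diaminopimelate epimerase of lysine synthesis, was 5.67-fold lower (limma, adjusted p = 0.0039). TPP2, tripeptidyl peptidase II, was 3.61-fold lower (adjusted p = 0.015), with pam48 samples 5 and 6 at the floor, the lowest level that the processing allows. AT5G47030, a subunit of the mitochondrial ATP synthase, was 3.75-fold lower (adjusted p = 0.015), with pam48 sample 4 at the floor and far from the other 5. In the other direction, AT2G36480 was 5.09-fold higher in pam48, at 2.72 ± 0.770 (SD, n = 6) against 0.37 ± 1.04 (SD, n = 6) in WT (limma, adjusted p = 0.012).

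AT2G38950 stood at the floor in all 6 pam48 samples and was at least 6.84-fold lower there (limma, adjusted p = 9.2e-04). That bound holds only for the quantile normalised values with each sample's own floor. With 1 common floor for all samples the change of AT2G38950 was -1.72 (log2). On the values as deposited it was -1.28, where the median probe was higher by 1.06. AT4G05030 was 6.15-fold lower, with 2 pam48 samples at the floor, and its change was -1.90 with the common floor. AT1G50000 was 4.56-fold lower, with 1 pam48 sample at the floor. AT5G27860 was 4.25-fold lower, with 2 WT and 4 pam48 samples at the floor, and its change was -1.26 (log2) with the common floor and 0.46 in numbers 5 and 6. Among the transcripts that were higher in pam48, AT4G35660 rose 6.30-fold (log2 change 2.66, and 2.04 without WT 3), AT4G38040 rose 5.51-fold, AT2G46300 rose 4.24-fold and AT5G39980, a pentatricopeptide repeat protein, rose 3.87-fold. PRA1.B6, a prenylated Rab acceptor, rose 3.74-fold, AT4G17260, an L-lactate dehydrogenase, 3.39-fold and AT3G11150 3.31-fold. AT4G38040 and PRA1.B6 each had 3 WT samples at the floor, and AT5G39980, AT4G17260 and AT3G11150 each had 1. Adjusted p in limma's test lay between 0.012 and 0.040 for the 8 genes named as higher. Of the 16 genes in these 2 paragraphs, 8 kept their call whichever sample was left out, among them PRK, TPP2, AT3G53580 and AT2G36480, and 8 lost it without at least 1 of the samples numbered 1 to 4 (highest adjusted p = 0.087). With consecutive numbers as a random block 14 of the 16 lost it, all but PRK and AT2G38950. AT4G35660, AT2G46300, AT5G39980, AT3G11150 and AT5G27860 did not pass with the common floor (adjusted p = 0.052 to 0.092). With the replicate number as a block, AT4G35660 (adjusted p = 0.057), AT2G46300 (0.072), AT5G39980 (0.056) and AT5G27860 (0.068) did not pass. Scaling ended 5 of the 16 calls with cyclic loess, 3 with median centring and 3 on the values as deposited, there AT5G27860, TPP2 (adjusted p = 0.083) and AT5G47030 (0.075). An exact permutation test per probe ended 6 (AT4G38040, AT2G46300, AT5G39980, PRA1.B6, AT3G11150 and AT5G27860, adjusted p = 0.069 to 0.084). PRK, AT2G38950, AT2G36480, AT3G53580, AT4G05030 and AT1G50000 kept their call in each of these cases other than the random block. Those cases all count consecutive columns as separate samples. With consecutive numbers averaged, all 16 genes lost the call. With a block on the averages, these 6 did not pass limma's test either (adjusted p = 0.089 to 0.19).

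**Figure D1:**
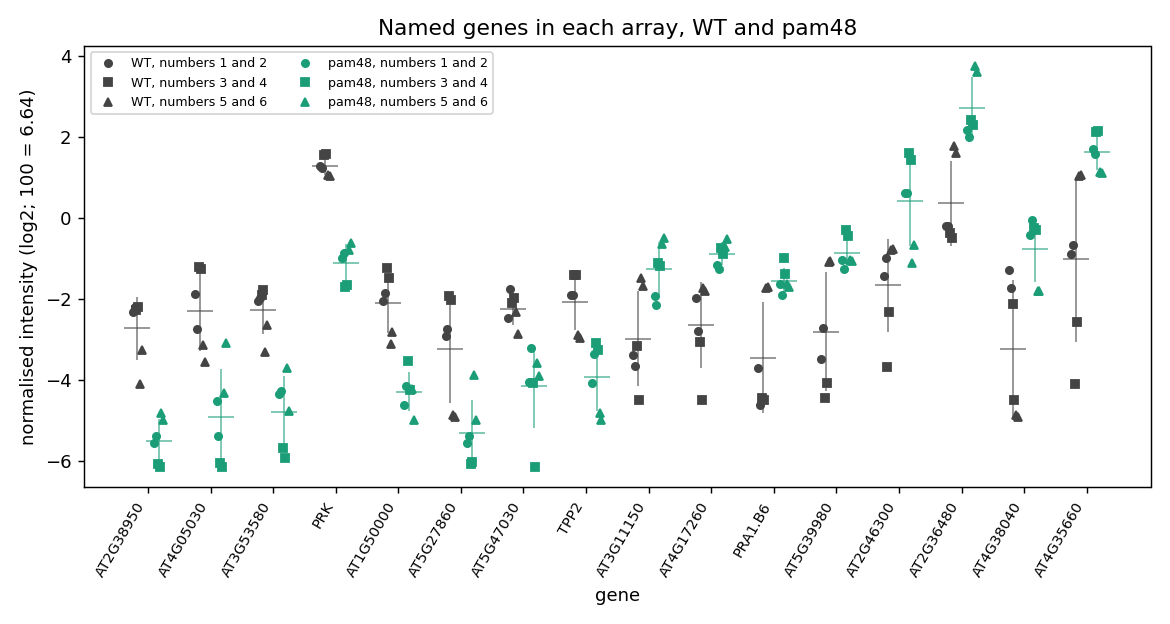
Normalised intensity (log2, vertical axis) of the 16 genes with the largest named changes (horizontal axis) in each of the 12 samples; grey is WT, green is pam48, shapes mark consecutive numbers, and bars give the mean ± SD (n = 6). For PRK the genotypes do not overlap, while for AT4G35660 the WT samples 5 and 6 lie close to the pam48 samples 5 and 6.

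Over all probes, 580 of 3439 passed limma's test with each column as a sample, 169 higher and 411 lower in pam48. The 452 with a measured fold, above the floor in at least 1 sample of each genotype, had a median of 2.38-fold for the 166 higher and 2.18-fold for the 286 lower. Of the 580, 42 lay at the floor in all 12 samples, where values carry no order, which leaves 538 (169 higher, 369 lower). The count of 580 fell to between 158 and 223 without any 1 of the 8 samples numbered 1 to 4. It rests on treating columns with consecutive numbers as separate samples. A split that keeps those couples whole but mixes the genotypes (WT 1 to 4 with pam48 1 and 2, against the rest) gave 464. Averaged in such couples (3 against 3), limma called 0 probes, with 386 at an unadjusted p under 0.05. With the couples as a random block it called 8 (3 higher, 5 lower), of which PRK (adjusted p = 0.0041), AT2G38950 (0.038) and AT3G09080 (3.51-fold lower, 0.019) have 1 gene name. The third was named after its values were seen. With the replicate number as a block, which pairs the samples, limma called 441 (188 higher, 253 lower), of which 333 were among the 580 and 42.6% were higher. That block still counts consecutive columns as separate samples. With the couples averaged and paired by a block, limma called 3. The balance of directions also depended on the scaling: 29.1% of calls were higher in pam48 after quantile normalisation, 40.3% after cyclic loess, and 95.3% of 1739 calls on the values as deposited, where the median probe was higher by 1.06 (log2). After quantile normalisation the median probe changed by -0.13. Relative to that median, PRK changed by -2.26 and AT2G36480 by 2.48, and relative to the median on the deposited scale by -3.06 and 1.52.

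Photosynthesis and plastid genes were asked about through lists fixed in advance, of which few members had a probe with 1 gene. Of 18 members with a probe, 4 passed the test over all probes and 14 did not. Of the 4, 3 were lower in pam48 and 1, AT5G65220, was at the floor in all 12 samples and has no measured change. Adjusted over the list alone, 8 passed, of which AT5G65220 is 1 and another 2, FATB and LHB1B2, are the single measured member of their list, so that their p is unadjusted. In 8 lists only 1 or 2 members were measured, so this adjustment is slight. Of all 3439 probes, 1107 had an unadjusted p under 0.05 in the same limma fit, so these passes do not set the list members apart. In the Calvin cycle list PRK was called and SBPASE, sedoheptulose-bisphosphatase, was not, at 0.30 ± 0.24 (log2 change, SE; adjusted p = 0.41). On the values as deposited it passed, at 1.37, where the median probe was higher by 1.06. Of the photosystem II subunits PSBY fell by 1.42 ± 0.40 (log2, SE; adjusted p = 0.037). PSBW gave 0.39 ± 0.26 (adjusted p = 0.31), and -0.995 with median centring (adjusted p = 0.099). On the values as deposited PSBW gave 0.11 (limma, adjusted p = 0.76). PSBY lost its call without any 1 of the 8 samples numbered 1 to 4 (highest adjusted p = 0.089), with consecutive numbers as a random block (adjusted p = 0.24), with cyclic loess (0.051) and in the exact permutation test (0.077).

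The photosystem I subunit PSAN gave -0.14 ± 0.20 (log2, SE; limma, adjusted p = 0.66), and with median centring it was lower by a change of -1.27 that passed (adjusted p = 0.0044). The light-harvesting gene LHB1B2 (LHCB1.5) gave -0.70 ± 0.25 (adjusted p = 0.068). It passed in 7 other settings, among them median centring (-2.05, adjusted p = 0.0012), the values as deposited (-0.95, 0.0083), array weights (0.0048), a variance prior with trend (0.041), and without pam48 5 (0.026) or pam48 6 (0.038). These settings count consecutive columns as separate samples. LHB1B2 did not pass limma's test with the random block (adjusted p = 0.39) or with couples averaged (0.49). The tetrapyrrole genes CHLM, magnesium protoporphyrin methyltransferase, and AT1G74470, geranylgeranyl reductase, gave -0.73 ± 0.31 and -0.63 ± 0.24 (adjusted p = 0.13 and 0.092). Both passed adjusted over the list alone, of which they were the only 2 measured members. AT1G74470 also passed with median centring (-1.37, adjusted p = 0.0020) and array weights (0.046), and CHLM with array weights (0.0033) and without pam48 5 (0.025), while CHLM gave 0.21 on the values as deposited (0.60), where the median probe was higher by 1.06. AT1G74470 gave -0.27 there (0.41). With the random block, adjusted p in limma's test was 0.43 for AT1G74470 and 0.51 for CHLM. With couples averaged it was 0.53 for both. AT3G58610, ketol-acid reductoisomerase of branched-chain amino acid synthesis, fell by 1.06 ± 0.28 (adjusted p = 0.030), a call lost without any 1 of the 8 samples numbered 1 to 4 (highest adjusted p = 0.072), with the random block (0.43) and on the values as deposited (-0.085, 0.76). Relative to the median probe on the deposited scale AT3G58610 changed by -1.14. AT3G23940, dihydroxyacid dehydratase of the same pathway, gave 0.38 ± 0.23 (adjusted p = 0.26), and passed on the values as deposited at 1.19 (0.011). FATB, an acyl carrier protein thioesterase, gave -0.97 ± 0.43 (adjusted p = 0.14, 0.032 with the replicate number as a block, and 0.27 with that block on averaged couples), and AT3G52960, a peroxiredoxin, gave 0.0079 ± 0.22 (adjusted p = 0.98). On the values as deposited AT3G52960 passed, at 0.84 (limma, adjusted p = 0.037), where the median probe was higher by 1.06.

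For plastid translation 6 ribosomal protein genes had a probe, with changes from -1.09 to -0.10 (log2) and a median of -0.57. The called member, AT5G65220, was the one at the floor in all 12 samples, and the other 5, which were not called, had a median of -0.32 (camera, adjusted p = 0.17). Of these 5, AT3G54210, named after its values were seen, gave -0.98 ± 0.40 (log2, SE; adjusted p = 0.11), 0.046 with the replicate number as a block and 0.28 with that block on averaged couples. Adjusted over the list alone, the only member called was AT5G65220. AT1G29070 gave -1.09 ± 0.40 (adjusted p = 0.080), and passed with array weights (0.0034) and without pam48 5 (0.032) or WT 6 (0.035). It did not pass limma's test with the random block (adjusted p = 0.44) or with couples averaged (0.43). The list of 6 did not pass camera's test with the preset correlation (p = 0.076), nor with an estimated correlation (p = 0.32). On the values as deposited the median of the list was 0.51, where the median probe was higher by 1.06. Limma's fry, which asks whether the genes move on balance in a single direction and does not compare them with other genes, gave an adjusted p = 0.021 for the 6, equal to the unadjusted value since 1 list was tested.

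The genotype difference was also measured within each couple of consecutive numbers. Across all probes, the change in numbers 1 and 2 correlated with that in numbers 3 and 4 (r = 0.69 across probes, which are not independent replicates). The change in numbers 5 and 6 followed them little, with r = 0.13 against 1 and 2 and r = 0.086 against 3 and 4. In the brightest 25% of probes these were 0.34 and 0.18, and that between 1 and 2 and 3 and 4 was 0.81. Changes of 2-fold or more were seen for 850 probes in numbers 1 and 2, for 1660 in 3 and 4 and for 389 in 5 and 6. PRK was lower in each couple, by -2.19, -3.25 and -1.75 (log2) in order of number, and so was TPP2, by -1.81, -1.77 and -1.98. TPP2 was at the floor in pam48 5 and 6, so the size of its change there depends on the floor. AT2G36480 was higher in each, by 2.28, 2.78 and 1.99. In contrast, AT4G35660 was higher by 2.43 and 5.47 in the lower-numbered couples and by 0.071 in numbers 5 and 6, AT2G46300 by 1.84 and 4.53 and then -0.12, and PSBY by -2.20 and -1.94 and then -0.14. Changes in numbers 5 and 6 were also small for PRA1.B6 (0.055), AT5G39980 (0.015) and AT4G05030 (-0.35). Without numbers 5 and 6 limma called 1527 probes, without 1 and 2 it called 10, and without 3 and 4 it called 11.

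**Figure D2:**
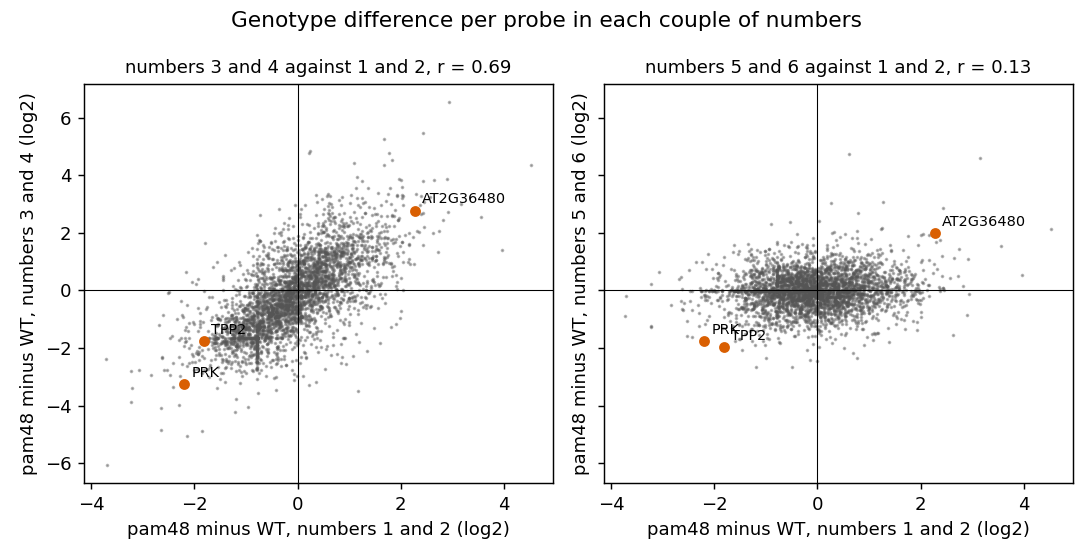
Genotype difference per probe (pam48 minus WT, log2), numbers 1 and 2 on the horizontal axes against numbers 3 and 4 (left) and 5 and 6 (right); each point is 1 of 3439 probes and orange points mark PRK, TPP2 and AT2G36480. The left cloud follows the diagonal (r = 0.69) and the right one does not (r = 0.13), while the 3 marked genes change the same way in every couple. TPP2 was at the floor in pam48 5 and 6.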

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

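The tests on other splits of the samples, on exchanged genotype labels, on a shared genotype and on a brightness trend were chosen after the result was seen, and that on odd and even columns before.

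AT5G47030, the mitochondrial ATP synthase subunit, stood out in pam48 because 1 sample lay far from the other 5: sample 4 was at the floor (-6.13, log2), while the others ran from -4.06 to -3.20. The gap was 0.707 of the range, above Dixon's 95% critical value. Among the 60 groups of 6 samples examined this was the only one. For 6 independent values chance alone gives about 1 in 20. Columns with consecutive numbers agree closely, so that rate need not hold here.

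Other splits of the samples do not settle whether chance can give the 580 calls made with each column as a sample. Of 100 splits of the 12 samples, drawn at random with the genotypes included, 1 reached 580 (highest other 168), as did 1 of the 32 that part all same-numbered couples of WT and pam48 (highest other 15), but nearly all of these place closely agreeing columns in opposite groups, which by itself keeps their counts low. The splits that keep consecutive numbers together are 10, too few for a share under 0.05: 1 of them, the genotypes, reached 580, and the highest other gave 464. With those couples averaged, 2 of the 10, the genotypes included, gave 386 or more probes at an unadjusted p under 0.05, and the highest other gave 418. In both cases the highest other split set WT 1 to 4 and pam48 1 and 2 against the rest, which is partly aligned with genotype. The remaining mixed splits are aligned to the same degree, so alignment alone does not account for the 464 or the 418. Mixed splits with all samples numbered 5 and 6 on the same side gave 464, 405, 181 and 39 calls. Mixed splits that part those samples gave at most 15. With couples averaged, the former gave 418, 369, 315 and 223 probes at an unadjusted p under 0.05, and the latter at most 248.

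Columns with consecutive numbers agreed most closely in 12 of 12 cases, which is what 2 readings of 1 hybridisation in a fixed order could give. If so, the difference between odd and even columns would partly belong to the probe and recur in every couple. Its correlation across probes was positive in all 15 combinations of the 6 couples but small, with a mean of 0.0516 and a range from 0.0070 to 0.206, which is neither the 0.1 or more in every combination that this needs nor the mean under 0.05 that would argue against it. Repeated readings and separate samples handled together therefore cannot be told apart, since either can make neighbours alike.

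Changes in numbers 5 and 6 followed those in 1 to 4 weakly. An exchange of genotype labels in 5 and 6 is argued against by the sign of the relation (r = 0.113 across probes, 95% interval 0.0797 to 0.146, for independent probes). A smooth trend with brightness in samples 1 to 4 is argued against by r = 0.646 between the other 2 couples after its removal. A single genotype on all samples numbered 5 and 6 cannot be told apart from a small genotype difference: of 615 probes that changed 2-fold or more the same way in 1 and 2 and in 3 and 4, 407 (66.2%) kept their sign in 5 and 6, but the share was 53.3% for pam48 5 and 65.4% or 67.5% for pam48 6 against the WT samples, and already 54.5% and 56.6% between samples of 1 genotype. What sets numbers 5 and 6 apart stays open, and no biological explanation was tested, since the labels give no factor for the numbers.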

How the results depend on the processing

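The alternatives with a common floor, with probes above the floor only, with averaged couples plus a block, and without a couple of numbers were chosen after seeing the data. Of the 580 calls (29.1% higher), the count and the share higher in pam48 became 1739 and 95.3% on values as deposited, 539 and 21.9% with median centring, 305 and 40.3% with cyclic loess, 360 and 40.6% without the dimmest 25%, 356 and 39.0% with an offset in place of the floor, 1248 and 35.0% with array weights, 377 and 35.8% with a common floor, and 358 and 37.2% among probes above the floor in all samples. The array weights were 0.34 to 0.59 in numbers 5 and 6 and 0.80 to 2.44 in numbers 1 to 4. Array weighting therefore partly repeats leaving out numbers 5 and 6. An adjusted p under 0.01 left 54 calls, of which 25.9% were higher. The replicate block, for same-numbered samples paired, gave 441 and 42.6%, with 333 of the 580 kept, and ended the call of 4 of the 16 genes with the largest changes and of AT5G65220, and added FATB and AT3G54210, which did not pass with the block on averaged couples. Averaging consecutive numbers gave 0 calls, averaging with a block 3 (100% higher), and the random block 8 (37.5%). Without numbers 1 and 2 there were 10 calls (50%), without 3 and 4 11 (45.5%), and without 5 and 6 1527 (37.5%), among them 573 of the 580. Leaving out 1 sample gave 158 to 678 calls, with 27.6% to 36.1% higher. The lowest, 158, came without WT 3 or without pam48 3, and counts fell to 223 or fewer without any 1 of the 8 samples numbered 1 to 4. The median of the 6 plastid ribosomal genes was -0.57, and 0.51 as deposited, where the median probe was higher by 1.06. The median of the list was -0.32 without the member at the floor (an alternative chosen after seeing the data; camera, adjusted p = 0.17) or without the dimmest 25% (0.087), -0.30 with the common floor (0.13), -0.27 with the offset (0.13), and -0.26 without numbers 3 and 4 (0.56). It was -0.72 with array weights (camera, adjusted p = 0.042) and -0.98 without numbers 5 and 6 (adjusted p = 0.016), where the list passed, as it did with fry (median -0.57). Leaving out 1 sample moved it from -0.70 to -0.47 (adjusted p = 0.044 to 0.13), and the list passed without pam48 5 or pam48 6. With an estimated correlation it did not pass on all samples (p = 0.32), and these lists of 6 hold AT5G65220, at the floor in all 12 samples. None of the 16 genes reversed under any alternative in which it was tested. They were chosen for large and separated changes, which makes a reversal unlikely. Blocks, averaging of couples, the variance prior and the permutation test leave the change itself as it was, so they could not reverse it. Under the random block 14 of the 16 lost the call, and under averaging all 16. Among list members, AT5G65220 reversed to 1.36 as deposited, 0.26 with median centring, 0.049 with loess and 0.017 with the offset, and CHLM to 0.21 as deposited. Relative to the median probe on the deposited scale CHLM changed by -0.85. PSBW reversed to -0.995 and AT3G52960 to -0.27 with median centring, PSAN to 0.0073 with loess, and AT3G52960 to -0.35 without numbers 3 and 4 and to between -0.084 and 0.095 when 1 sample was left out. The cause of these differences was otherwise not tested, except that floor values carry no order. Averaging leaves fewer samples, but the random block kept all 12 columns and called 8. It estimated a correlation of 0.81 between the columns of a couple. A smaller number of columns therefore does not account for the calls lost with the random block. The list test was not run with the random block, the other variance prior or the permutation test, and the criterion for averaging columns from the start was not met. Values near the floor limit what can be read for dim probes.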

Other observations

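The genes in this part were chosen after their values were seen. Leaving out probes at the floor in all 12 samples, 66 probes changed 2-fold or more in the same direction in each couple of consecutive numbers, 28 higher and 38 lower in pam48. With genotypes exchanged in numbers 5 and 6 that count was 29, in 3 and 4 it was 0, and in 1 and 2 it was 1. The changes in 1 and 2 and in 3 and 4 ran together (r = 0.69), so the counts of 0 and 1 had to be low. Only the 29 can be set against the 66. Among the 66 were 16 probes with 1 gene, 5 higher and 11 lower. AT-HF, which encodes a bifunctional enzyme of histidine synthesis, was 3.29-fold higher, at -0.08 ± 0.451 (log2, SD, n = 6) in pam48 and -1.80 ± 0.877 (SD, n = 6) in WT (limma, adjusted p = 0.015). AT3G09080 was 3.51-fold lower (adjusted p = 3.1e-04). AT1G76450 was 3.39-fold lower, AT2G28790 3.28-fold, AT5G66530 2.94-fold and AT1G15140 2.25-fold, with adjusted p from 0.0057 to 0.021. Of these 6 only AT3G09080 passed with consecutive numbers as a random block.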
